A study of Mus musculus with 8 samples.

How the data were processed

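Expression was measured in the gastrocnemius, a fast-twitch calf muscle, of 24-week-old C57BL/6 mice, 4 wild type and 4 with a knockout of Anxa2. Anxa2 encodes annexin A2, a calcium-dependent protein that binds phospholipid membranes. Per the labels' protocols, total RNA was taken with Trizol from frozen left-hindlimb muscle, cleaned on columns, and turned into biotin-labelled cRNA with an Affymetrix kit that primes at the 3' end of transcripts. One array was run for each animal. A 3'-primed label reports the part of a transcript near its poly(A) tail, so a deletion elsewhere in a gene need not lower its signal.

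The deposited values are log2 expression values. The submitters' processing notes name RMA, which corrects background, equalizes the distribution of probe intensities across arrays and summarizes the probes of a set, and R 3.1.2. The probe-set definition, the filters and the scan dates are not given in the sources used here. The value table has 17352 rows without missing values, and each row is an Ensembl mouse gene ID with the suffix _at, so that each gene has 1 row. It has 0 Affymetrix control rows, and no detection call or count came with it. The precision is limited by the number of arrays and by how unevenly they vary. The values were checked to be on a log2 scale without centring per gene: the lowest value of an array lies between 1.94 and 2.07 and the highest between 14.5 and 14.6, with a median between 4.95 and 5.09.

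The name table used here, of the GRCm38.p6 assembly, lists 49997 genes, 0 of them with an Ensembl ID, so 0 of the 17352 rows were matched to a symbol. Rows are therefore given by the ID in the file, at most 2 higher and 2 lower in the knockout, and no coordinates are given. For the same reason the row of Anxa2 was not looked up, and the 43 gene lists fixed before the data were examined (annexins, membrane repair, fibre types, metabolism, inflammation, cell types, the chromosomal neighbours of Anxa2 and others) were not analysed here. The rule fixed in advance took the genes past the threshold with the largest change, and, where fewer than 5 passed, those with the smallest unadjusted p. With 0 past the threshold, the 2 rows with the smallest p in each direction are given.

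Knockout and wild type were compared with limma 3.58.1 in R 4.3.3. A linear model with the group as its only term was fitted to each row over all 8 arrays, followed by empirical Bayes moderation with the default settings, two-sided p-values and Benjamini-Hochberg adjustment over all 17352 rows. The threshold was an adjusted p of 0.05. No low-value filter was used. Intervals are 95% intervals of the moderated fit and are not adjusted for the number of rows. Principal components were taken from the row-centred values of the 8 arrays.

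The fit was tested on simulated data drawn from each row's mean and residual spread, with 200 of the 17352 rows changed by a known fold. At 1.5-fold, 43.5% of the changed rows were recovered in the right direction, at 2-fold 79.5%, at 3-fold 94.5% and at 4-fold 97.5%, with between 4 and 12 false calls per run. With no change simulated, 0 rows passed the threshold and 940 had an unadjusted p under 0.05. The simulation draws arrays that vary independently and alike, which the real arrays did not. It also changes 200 rows at once, which makes the adjusted threshold easier to pass than with few changed rows. The recovered shares therefore overstate what the fit would find where few rows differ.

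Alternatives fixed before the data were examined were the replicate number as a block, filters at the 25th and 50th percentile of mean level, an intensity trend with robust moderation, array weights, centring of each array on its median, renewed quantile normalization, a minimum change of 1.5-fold, an adjusted p under 0.10, and leaving out each array in turn. A block for a split of the arrays seen in the data, cyclic loess normalization and a fit without the 2 arrays highest on the first component were added after seeing the data. Alternatives on how probe sets of a gene are combined did not apply, because each gene has 1 row, and those on gene lists were not run. All 35 splits of the 8 arrays into 4 and 4 were fitted the same way. Figures were drawn with matplotlib 3.10.9.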

Results

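Gastrocnemius RNA of 4 wild-type mice and 4 Anxa2 knockout mice, all 24 weeks old, was profiled on 8 arrays. The labels number the samples of each genotype as biological replicates 1 to 4. The series concerns the part that annexin A2 plays in muscle repair, and its design holds a single comparison, knockout against wild type. The table gave an RMA log2 value for 17352 genes, each a row named by its Ensembl ID. Median log2 values lay between 4.95 in wild type replicate 2 and 5.09 in wild type replicate 4. No pair of arrays was identical, and the correlation of a pair across rows ran from 0.974 to 0.995.

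The row with the smallest p was ENSMUSG00000032231_at, which was lower in every knockout array than in any wild-type array. Its mean log2 value was 8.86 ± 0.30 (SD, n = 4) in wild type and 7.39 ± 0.22 (SD, n = 4) in the knockout. The wild-type arrays read 8.66, 8.56, 9.08 and 9.15, and the knockout arrays 7.28, 7.15, 7.61 and 7.54. The difference of -1.47 (SE 0.16, 95% interval -1.83 to -1.11) corresponds to a level 2.77-fold lower in the knockout. Its limma p was 3.7e-06 before adjustment and 0.065 after Benjamini-Hochberg adjustment over all rows, so that it missed the threshold of 0.05. The adjusted p passed the threshold in 5 of 18 alternative fits and ranged from 0.021 to 0.48 over the 18. The row is not paired with a gene name in the sources used here, and the row of the targeted gene, Anxa2, was not looked up.

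**Figure D1:**
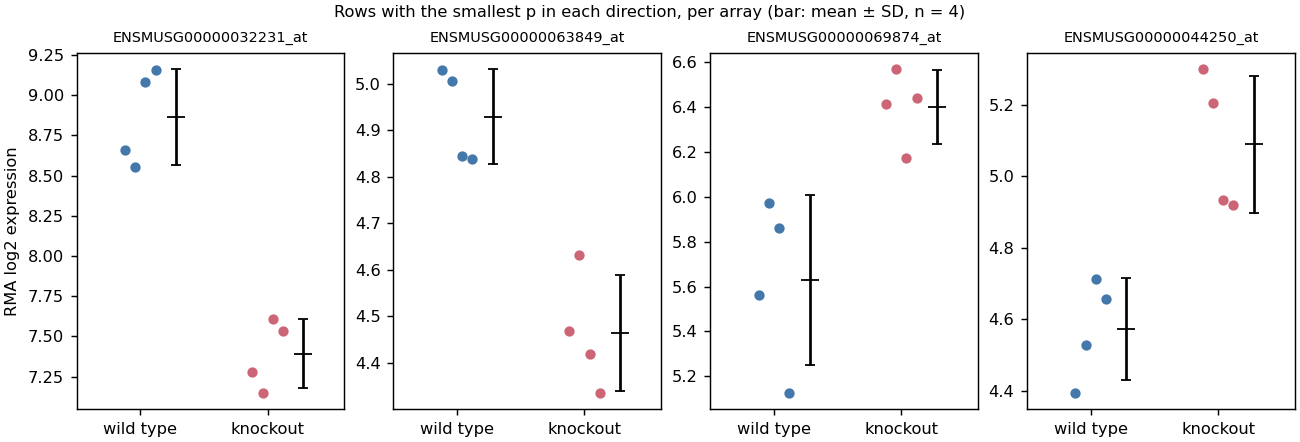
RMA log2 expression of the 2 rows lower and the 2 rows higher in the knockout with the smallest p, 1 point per array, with the mean and SD of 4 arrays beside the points. Each panel has its own vertical scale. In ENSMUSG00000032231_at the knockout arrays lie between 7.15 and 7.61 and the wild-type arrays between 8.56 and 9.15.

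Across all rows, 0 genes were higher and 0 were lower in the knockout at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05, limma gave 127 rows with a higher and 142 with a lower mean in the knockout, 269 in all, where 868 would be found with no effect and independent, evenly varying arrays. Limma with an intensity trend and robust moderation also called 0 rows in either direction, and limma with array weights called 1 row, the lower ENSMUSG00000032231_at. With each array centred on its median, the unadjusted counts were 111 higher and 217 lower, and with array weights they were 413 and 264. They were 255 and 155 without wild type replicate 4, 228 and 173 without wild type replicate 3, and 277 and 253 without knockout replicate 2. The balance of higher and lower rows thus depended on the scaling and on single arrays of both genotypes. The total of 269 was 530 without knockout replicate 2 and 410 without wild type replicate 4. In 227 rows, 1.31% of the total, the 4 knockout arrays all lay on the same side of the 4 wild-type arrays, with 105 higher and 122 lower. Chance alone separates 2.86% of rows in this way.

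After ENSMUSG00000032231_at, the next smallest adjusted p was 1.00. The second row in the lower direction was ENSMUSG00000063849_at, at 4.93 ± 0.10 in wild type and 4.46 ± 0.12 in the knockout (SD, n = 4), a difference of -0.47 (SE 0.10) with a limma adjusted p of 1.00. In the higher direction, ENSMUSG00000069874_at read 5.63 ± 0.38 in wild type and 6.40 ± 0.16 in the knockout (SD, n = 4). This difference was 0.77 (SE 0.18), or 1.70-fold, with a limma adjusted p of 1.00. ENSMUSG00000044250_at read 4.57 ± 0.14 in wild type and 5.09 ± 0.19 in the knockout (SD, n = 4), a difference of 0.52 (SE 0.12), or 1.43-fold, with a limma adjusted p of 1.00. In these 3 rows no knockout array overlapped a wild-type array, and the differences are values that did not pass the test. None of the 3 passed in an alternative fit that tested it, and none of the 4 rows changed sign there. The filter at the 50th percentile of mean level left out ENSMUSG00000063849_at and ENSMUSG00000044250_at.

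**Figure D2:**
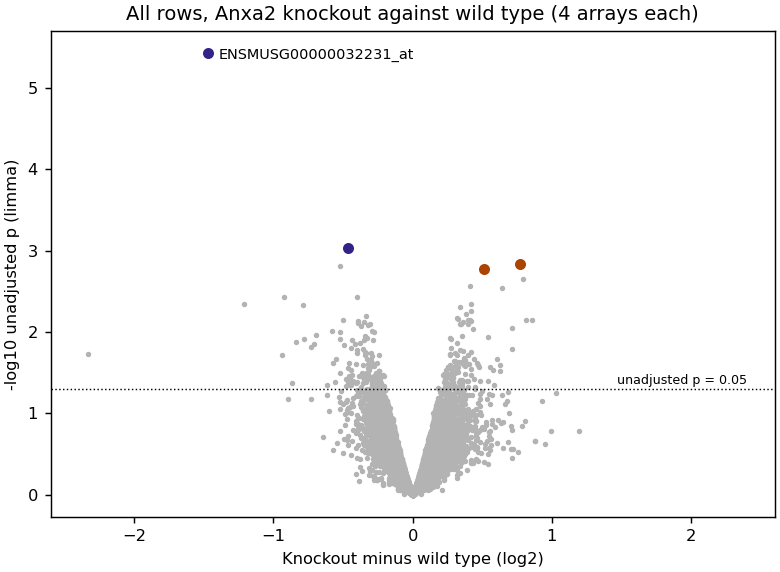
Difference between knockout and wild type (log2, horizontal) against the negative log10 of the unadjusted limma p (vertical) for all 17352 rows, with the 4 rows named in the text in colour and the dotted line at an unadjusted p of 0.05. ENSMUSG00000032231_at stands alone at -1.47 with a p of 3.7e-06.

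Differences of more than 2-fold were rare among the measured means. The knockout mean was over 2-fold lower in 3 rows and over 2-fold higher in 2, and in 2 of these 5 rows the arrays of the groups did not overlap. For 17077 rows, 98.4% of the total, the 95% interval of the difference lay within a 2-fold change either way. For 15118 rows, 87.1%, it lay within a 1.5-fold change. The remaining 275 rows had intervals that reached 2-fold, so that a change of that size was not excluded for them. These intervals refer to the RMA scale, which compresses differences near the background.

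The width of the intervals differed little between levels of expression. Among the 4338 rows with the lowest mean level (log2 2.17 to 3.63), the median half-width of the 95% interval was 0.26, and 99.4% of intervals lay within 2-fold. Among the 4338 rows with the highest mean level (6.67 to 14.6) the median half-width was 0.32, and 96.9% lay within 2-fold. At an unadjusted p under 0.05, the lowest of these 4 level classes held 10 higher and 34 lower rows and the highest held 33 higher and 31 lower. The classes between them held 32 higher and 33 lower rows, and 52 higher and 44 lower, in order of level. With no effect, 217 rows of each class would be found.

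Arrays of the same genotype were no more alike than arrays of different genotype. The mean correlation across rows was 0.987 for pairs within a genotype and 0.988 for pairs between genotypes. The first principal component held 45.0% of the variance and the second 14.5%, and neither separated the genotypes. Wild type replicate 4 had a score of 46.5 on the first component, while the other wild-type arrays lay between -12.7 and -3.47. Its mean correlation with the other 7 arrays was 0.978, against 0.988 to 0.991 for each of the others. Knockout replicate 2 had the next highest score, 13.8. In a fit without these 2 arrays, chosen after seeing the data, limma called 0 rows in either direction, and 435 rows had a higher and 266 a lower mean at an unadjusted p under 0.05. In that fit the difference of ENSMUSG00000032231_at was -1.29 (SE 0.15).

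**Figure D3:**
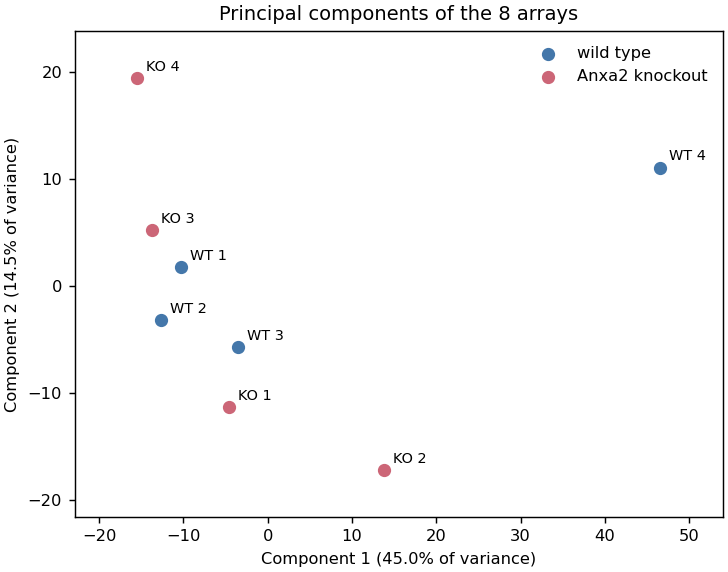
Scores of the 8 arrays on the first 2 principal components of the log2 values, with the share of variance on each axis and colour by genotype. Wild type replicate 4 (WT 4) lies at 46.5 on the first component, apart from the other arrays, and the genotypes overlap.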

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

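The tests on wild type replicate 4 and on uneven arrays in this part were chosen after the values were seen. For each genotype, 5 measures per array and the 4 rows named in the report were checked for 1 array far from the other 3, and 5 of these 18 checks found one, where chance gives about 1 in 20. The checks are not independent, and all 5 fell on wild type replicate 4 or knockout replicate 2.

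Wild type replicate 4 was far from the other wild-type arrays in its mean correlation with the other 7 arrays (0.978 against 0.989 to 0.990), in its first component score (46.5 against at most -3.47) and in the SD of its deviations from its group (0.430 log2 units against 0.244 to 0.257). Knockout replicate 2 was far from the other knockout arrays in its median (5.04 against 5.01 in each of the others) and in its interquartile range (2.88 against 3.13 to 3.16). Wild type replicate 4 lay in the same direction on both measures, although neither counted as far in these checks. Its median of 5.09 was the highest of all arrays. Its interquartile range was 2.77, against 3.06 to 3.15 in the other wild-type arrays. A shift of signal that depends on the level of expression is argued against as the whole source for wild type replicate 4, since a smooth curve on mean level took up only 0.109 of the variance of its deviations. The same curve took up 0.143 in knockout replicate 2 and 0.011 to 0.085 in the remaining arrays. Such a shift therefore stays open as a part of the source. A knockout sample under a wild-type label is argued against by ENSMUSG00000032231_at, the row with the smallest p among the other 7 arrays. On a scale with the knockout mean at 0 and the mean of the other wild-type arrays at 1, wild type replicate 4 lay at 1.28, and the knockout arrays had an SD of 0.157. Its deviations across rows correlated at 0.467 with those of knockout replicate 2, and at -0.056, -0.259 and -0.239 with those of knockout replicates 1, 3 and 4. Deviations within a group offset each other, so positive and negative values come together. The highest value, 0.467, is compatible with a source of variation that reached arrays of both genotypes, but does not establish one. RNA quality, dissection and cell composition stay open, and no biological explanation was tested here, because the labels give no factor other than genotype. The split of the arrays described under the other observations stays open as well. Wild type replicate 4 and knockout replicate 2 both lie on its second side, but so does knockout replicate 1, at -0.056.

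The genotype comparison gave fewer small p-values than an even spread, 269 against 868. Array weights raised the count 2.52 times to 677, and leaving out wild type replicate 4 and knockout replicate 2 raised it to 701, so these 2 arrays may account for much of the shortfall. Among the 35 splits, the median count was 1122 where these 2 arrays lay on the same side and 371.5 where they lay on opposite sides, as they do by genotype. Whether the split of the arrays described under the other observations also adds to the spread stays open: as a block it raised the count 1.43 times, with a range of 0.896 to 3.48 when each array was left out in turn.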

How the results depend on the processing

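Counts were recomputed under 20 alternatives, and 0 rows were higher in the knockout in all of them. The count of lower rows was 0 in 14 and 1 in the other 6: with the replicate number as a block, array weights, median centring, quantile normalization, an adjusted p under 0.10, and cyclic loess, which was chosen after seeing the data. The row was ENSMUSG00000032231_at each time. Its adjusted p was 0.032 with the replicate block, where its difference kept the value of -1.47 and its SE fell from 0.16 to 0.11. Deviations of same-numbered arrays from their group means correlated at -0.072, -0.25, 0.18 and -0.24, which gave no regular sign that the numbers pair the samples. Pairing is not excluded, since single arrays such as wild type replicate 4 weigh heavily in these deviations. Same-numbered arrays also lie on opposite sides of the split described under the other observations, which can lower these correlations. The block changed no other call, and it gave 279 rows at an unadjusted p under 0.05 against 269. Leaving out each array in turn gave 0 rows lower or higher each time, and an adjusted p for that row between 0.072 and 0.48, with 7 arrays in place of 8. Its log2 difference lay between -1.57 and -1.29 over 18 fits. The count of rows whose interval lay within 2-fold went from 17077 to 8451 under the median filter, because only 8676 rows were then tested. The unadjusted count of 269 rows ranged from 198, without knockout replicate 1, to 530, without knockout replicate 2, when each array was left out in turn. It was over 1.5 times as high without knockout replicate 2 and without wild type replicate 4 (410). The median of all differences shifted by at most 0.025 (log2). Alternatives on combining probe sets and on gene lists were not run.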

Other observations

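The tests of splits by unadjusted p were chosen after the values were seen, while the 3 tests on the split below were written down before their results. At an adjusted p of 0.05 genotype gave 0 rows, so that all 35 splits of the 8 arrays into 4 and 4 reach its count by construction and their number says nothing about chance. The highest other split gave 50. At an unadjusted p under 0.05, 33 of the 35 splits gave as many rows as the 269 of genotype, and the highest other split gave 1940. Chance can therefore not be excluded for the count of 269.

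The split with 50 rows set wild type replicates 1 and 2 with knockout replicates 3 and 4 against wild type replicates 3 and 4 with knockout replicates 1 and 2, and it was found by its count. Only 1 other split had any row past the threshold, and it had 1. Of the 50 rows, 19 were higher on the first side and 31 on the second. ENSMUSG00000086503_at read 9.25 ± 0.28 on the first side and 3.82 ± 0.26 on the second (SD, n = 4), with a limma adjusted p of 5.7e-08. ENSMUSG00000069045_at read 2.66 ± 0.06 and 8.71 ± 0.26 (SD, n = 4), higher on the second side with a limma adjusted p of 2.8e-09. The low side of ENSMUSG00000069045_at lies near the bottom of the range, and that of ENSMUSG00000086503_at just above 3.63, the top of the lowest level class. No detection call shows either to be above background, so no exact fold is given. Both IDs were chosen after their values were seen, as the rows with the largest difference each way.

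This points to a structure of the samples that crosses genotype, with 2 animals of each genotype on each side. A level-dependent shift of signal is argued against, since 49 rows passed after cyclic loess, and so is wild type replicate 4 alone, since 53 rows passed without it. Leaving out each array in turn gave 29 to 53 rows. A candidate explanation is animals of 2 sexes. It predicted at least 1 row over 8-fold apart in each direction without overlap, and there was 1 such row higher on the first side and 2 higher on the second. The labels used here give no sex and name no batch, and the rows are not paired with gene names, so it remains a hypothesis. As a block in the genotype fit, chosen after seeing the data, the split left 0 rows past the threshold in either direction, and the adjusted p of ENSMUSG00000032231_at was 0.119.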
